A study of Mus musculus with 3 samples.

How the data were processed

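Gene counts from 3 single-cell RNA libraries of mouse lung epithelium were analysed. The deposited values are raw UMI counts, whole numbers of RNA molecules per gene and cell barcode, in 1 matrix per library, per the file headers. The submitters' processing notes name Cell Ranger 3.0.2 and the mm10 build; the annotation release is not given in the sources used here. The libraries were made with a 3' kit, so each count stands for a molecule read near the end of its transcript. Per the labels, immune and endothelial cells were depleted, cells with the surface protein EPCAM were taken, and these were sorted by the GFP reporter. All 31053 features of the matrices were used, with gene symbols and Ensembl identifiers as the files give them. Coordinates come from the GENCODE annotation of the same mouse build, matched by Ensembl identifier.

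Group and genotype were taken from the labels. The control library holds both GFP fractions in equal parts. Each mutant library holds 1 fraction, but the labels do not say which is GFP-positive. The mutant libraries are therefore called mutant 1 and mutant 2, were never averaged, and are not replicates of each other. With 1 library on each side of every comparison there is no test, no p-value and no count of changed genes. Counts have exact Poisson 95% intervals, shares exact binomial (Clopper-Pearson) 95% intervals, and ratios of counts conditional exact intervals. All these intervals cover counting error only, not differences between animals, sorts or library preparations.

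The matrices hold 16638 barcodes in control, 36830 in mutant 1 and 57304 in mutant 2. Barcodes with at least 500 detected genes and a mitochondrial share under 20% were kept, which left 8079, 34528 and 9330. Median UMIs per kept barcode were 1461, 1640 and 1355. Barcodes under 500 genes (8317, 2149 and 47804) were summed per library and used as an estimate of free RNA, the RNA of broken cells that enters every droplet. These barcodes were called as cells in the filtered matrices, so the estimate may hold small or damaged cells as well. In mutant 2 it does hold cells. At a minimum of 250 genes that library had 3543 mesenchymal-like, 1032 neuroendocrine-like and 162 AT1-like barcodes, against 665, 93 and 7 at 500 genes. Levels set against free RNA are therefore not levels over pure background, above all in mutant 2.

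Kept barcodes of all libraries were clustered together, with no correction between libraries. Counts were scaled per barcode and log-transformed, 2000 variable genes were reduced to 30 principal components, and Leiden clustering at resolution 1 was run on a graph of 15 nearest neighbours. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9. Clusters were named "X-like" from 18 marker sets. A named cluster needed at least 3 markers of 1 set raised by a log2 of 0.5 over the mean of the 3 libraries' profiles, with 20 CPM added to both, and a mean marker log2 of at least 0.2 over free RNA. It also needed more markers of that set among its 10 leading genes than of any other set. A cluster with no marker among them needed a mean marker log2 of at least 1 and a depth of at least 1/3 of the library median. These naming thresholds were set after it was seen which clusters they named. Gene minimums of 500, 1000 and more and 3 ways to form the fold of a marker were explored on the way, and 2 neighbour graphs were tried. The pruned shared-neighbour graph was made the main one for a time because its clusters looked cleaner; that was undone before any comparison between libraries was computed, and it is now an alternative. Clusters without a name make up 10.9% of control, 74.0% of mutant 1 and 1.40% of mutant 2 barcodes.

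Doublets were to be removed with a score against simulated doublets. The score's threshold called 92.2%, 98.5% and 82.9% of the barcodes of control, mutant 1 and mutant 2, so the caller did not work and all barcodes were kept; removing the 5% with the highest score was added as an alternative.

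UMIs were summed per library and class and given as UMIs per 1000000 UMIs (CPM). A class was compared where all 3 libraries held at least 50 of its barcodes, and under the alternatives where both libraries compared held at least 20. Deuterosomal-like barcodes numbered 2 in mutant 2, so only their numbers and Cdh1 level are given. AT2-like barcodes of mutant 1 numbered 48, so mutant 2 alone was compared with control in that class, a choice made after the data were seen. A count of 0 was set to 3 UMIs to give a bound on a ratio. The rule for naming genes was as follows. A gene needed 100 UMIs over the libraries compared and a CPM of 20 in 1 of them. Mitochondrial and ribosomal protein genes, and genes under a 10th of their level in another class in every library, were left out. Genes were then ranked by the bound of the log2 interval nearest to 0. The 12 highest and 12 lowest with the same sign in both mutant libraries were taken for club-like barcodes, 8 and 8 between the mutant libraries, and 5 and 5 for other classes, with up to 4 members of each list. Of the genes so chosen, 1 is not reported here. Among the genes so chosen, those that lead a class's own clusters are named as such and are not treated as results, while list medians hold them unless stated. For 22 gene lists, the median log2 ratio of members with at least 100 UMIs is given where at least 3 were measured. Its percentile is its place among 10000 random lists of the same size matched on expression, as a description of these libraries.

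The ratio, its interval, the ranking and the list percentile were tested on simulated Poisson counts drawn from the real totals, with 200 genes changed by known folds. Both sides of a comparison shared 1 profile otherwise. Filtering, clustering, naming, free RNA and unlike classes were not tested by it. In the club-like comparison of mutant 1 with control, run on 4857 genes, the interval held the true value for 96.0% of unchanged genes. It held it for 100% of genes at a fold of 2 and for 90% at a fold of 4. The 12 highest genes by the ranking were all among those raised, and a simulated list of 20 genes raised by a fold of 2 stood at the 100th percentile. In mesenchymal-like barcodes of mutant 2 the interval held the true value for 88% of genes at a fold of 0.25. In ciliated-like barcodes of mutant 2 it excluded no change for 76% at a fold of 0.5.

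The marker sets, the gene lists, the rule for naming genes and the following alternatives were set before the data were examined. They were minimums of 1000 and 250 genes, a mitochondrial limit of 10%, resolution 0.5, libraries clustered apart, CPM without the 20 most abundant genes, median-of-ratios scaling, the mean over barcodes, thinning to 3000 UMIs, subtraction of free RNA, and a list minimum of 20 UMIs. The shared-neighbour graph and the doublet score removal were added after the data were seen. Keeping doublets was to be another alternative; it equals the main setting and was not run apart. The GFP transgene is not among the features used here, and the exons deleted by Cre are not given in the sources used here.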

Results

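Single-cell RNA sequencing measured gene expression in EPCAM-positive lung epithelial cells of C57BL/6J mice aged 8-12 weeks. The mice carried a Cre recombinase that acts after tamoxifen, driven by Scgb1a1, the gene of the main secretory protein of airway club cells, and a Sun1-GFP reporter that marks nuclei of cells in which Cre has acted. Control mice had 1 floxed copy of Cdh1, the gene of the epithelial adhesion protein E-cadherin, and mutant mice had both copies floxed. The design asks how airway epithelial cells differ when club cells lose E-cadherin. There was 1 control library, with GFP-positive and GFP-negative cells in equal parts, and 2 mutant libraries, 1 for each GFP fraction, here called mutant 1 and mutant 2 because the labels do not tell which fraction is which. The libraries held 26217234 UMIs in control, 76079664 in mutant 1 and 45219315 in mutant 2. With 1 library per population there were no replicates, so all values describe these libraries, and every interval is a 95% interval for counting error only.

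The libraries held different cell populations. Alveolar type 2 (AT2)-like barcodes made up 38.0% of control (3066 of 8079, interval 36.9 to 39.0), 0.139% of mutant 1 (48 of 34528, 0.103 to 0.184) and 79.9% of mutant 2 (7455 of 9330, 79.1 to 80.7). Ciliated-like barcodes made up 23.9% of control, 19.8% of mutant 1 and 3.65% of mutant 2. Club-like barcodes made up 23.2%, 1.47% and 6.82%, numbering 1876, 506 and 636. Mesenchymal-like barcodes made up 1.83%, 0.866% and 7.13%, although the sort took EPCAM-positive cells. Deuterosomal-like barcodes, precursors of multiciliated cells, numbered 136 in control, 1292 in mutant 1 and 2 in mutant 2, neuroendocrine-like ones 25, 23 and 93, and AT1-like ones 16, 0 and 7. The 0 in mutant 1 allows a share of up to 0.0107%. A further 74.0% of mutant 1 barcodes fell in clusters left without a name, against 10.9% in control and 1.40% in mutant 2. The goblet set came nearest in 2 of these clusters, with 8531 and 6601 mutant 1 barcodes, and the latter had 8 goblet markers raised but a mean marker log2 over free RNA of 0.198, where 0.2 was asked. In these shares the sort cannot be separated from genotype, since control mixes the GFP fractions equally and each mutant library is 1 fraction, so they are not read as an effect of genotype. They also depended on the clustering. With the shared-neighbour graph, ciliated-like barcodes made up 1.05% of mutant 1, and club-like ones 7.71% of mutant 1 and 0.332% of mutant 2.

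Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246, plus strand, mm10) was lower in mutant 1 than in control in ciliated-like barcodes, and higher in mutant 2 than in control in club-like barcodes. In club-like barcodes its level was 148 CPM in control (interval 137 to 160), 125 CPM in mutant 1 (105 to 148) and 294 CPM in mutant 2 (256 to 336). The log2 ratio to control was -0.25 in mutant 1 (-0.53 to 0.02), an interval that holds 0, and 0.99 in mutant 2 (0.76 to 1.21). Ciliated markers lay a median log2 of 2.74 above free RNA in club-like barcodes of mutant 2 and at -0.32 in those of control. The mutant 2 ratio therefore compares unlike barcodes. In ciliated-like barcodes Cdh1 stood at 305 CPM in control, 150 CPM in mutant 1 and 321 CPM in mutant 2, with log2 ratios of -1.02 (-1.12 to -0.93) and 0.07 (-0.18 to 0.32). Within the ciliated-like cluster that held most of the mutant 1 barcodes, it stood at 251 CPM in control and 150 CPM in mutant 1, a log2 ratio of -0.74 (-0.91 to -0.57). Over the whole class, ciliated markers lay above free RNA by a median log2 of 1.91 in control and 0.46 in mutant 1. Its mutant 1 ratio thus compares unlike barcodes too. In mesenchymal-like barcodes Cdh1 stood at 221, 113 and 155 CPM, with log2 ratios of -0.96 (-1.55 to -0.38) and -0.51 (-0.98 to -0.02). The control and mutant 1 levels there rest on 51 and 53 UMIs. Their intervals, 165 to 291 and 85 to 148 CPM, hold the free RNA levels given below. In AT2-like barcodes Cdh1 was 209 CPM in control and 191 CPM in mutant 2, a log2 ratio of -0.13 (-0.23 to -0.04). In the barcodes outside any named class it was 168 CPM in control and 106 CPM in mutant 1, a log2 ratio of -0.66 (-0.84 to -0.48). In deuterosomal-like barcodes it was 137 CPM in control and 107 CPM in mutant 1, a log2 ratio of -0.36 (-0.84 to 0.16). Free RNA held Cdh1 at 188, 138 and 196 CPM in control, mutant 1 and mutant 2. The mutant 1 levels lay near or under that library's background. So did those of club-like, AT2-like, mesenchymal-like, deuterosomal-like and unnamed barcodes in control, and of AT2-like and mesenchymal-like barcodes in mutant 2. The Cdh1 ratio of club-like barcodes in mutant 1 turned positive, at 0.38, with a mitochondrial limit of 10%, at 0.33 without the highest doublet scores and at 0.40 after thinning to 3000 UMIs, and was lower under the 3 other scalings, at -0.67, -0.64 and -0.57. The same scalings gave 0.55, 0.47 and 0.59 in mutant 2. UMIs from the 3' end may lie outside the deleted exons, which are not given in the sources used here, so these counts check nothing about the deletion.

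**Figure D1:**
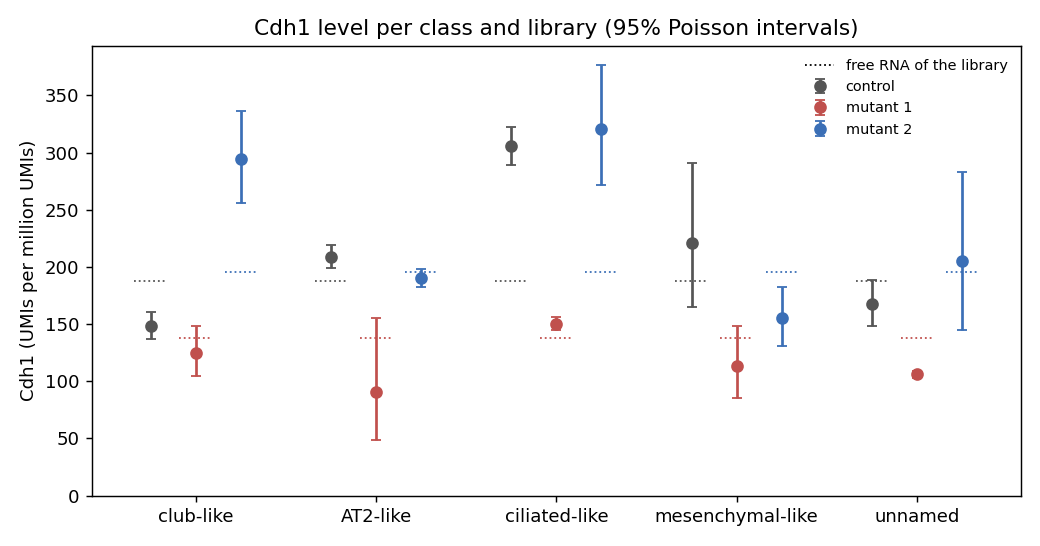
Cdh1 level in UMIs per 1000000 UMIs (CPM) for 4 named classes and the unnamed barcodes in control, mutant 1 and mutant 2, with points for the summed level, bars for exact Poisson 95% intervals and dotted lines for the free RNA of the same library. In ciliated-like barcodes mutant 1 lies at 150 CPM against 305 CPM in control and 321 CPM in mutant 2.

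Club-like barcodes, a class named after the cell type that carries the Cre driver, held more interferon response and MHC class I list RNA in both mutant libraries than in control. They also held more RNA of the keratin list in mutant 1, and less of the xenobiotic metabolism list in both. Club markers lay above free RNA for 13 of 13 in control, 4 of 13 in mutant 1 and 7 of 12 in mutant 2. The ratios of both mutant libraries to control therefore compare unlike barcodes and need not describe club cells. Keratin genes and the epithelial marker Sfn were higher in both: Krt8 stood at 399 CPM in control, 810 CPM in mutant 1, near the 825 CPM of its free RNA, and 827 CPM in mutant 2, and Sfn at 99.1, 287 and 279 CPM. Lgals3, which encodes galectin-3, was at 122 CPM in control, 698 CPM in mutant 1 and 419 CPM in mutant 2, and Areg, which encodes the EGF receptor ligand amphiregulin, at 97.0, 701 and 518 CPM. The antigen-presentation genes B2m and H2-D1 were higher in both mutant libraries, with log2 ratios of 1.48 (1.30 to 1.66) and 1.12 (0.96 to 1.28) in mutant 1 and of 1.15 (0.92 to 1.37) and 1.39 (1.22 to 1.55) in mutant 2. Cbr2, a carbonyl reductase and one of the club markers, was lower in mutant 1, at 2298 CPM against 6710 CPM in control.

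The named genes that were higher in both mutant libraries were Xist, Basp1, AU040972, Areg, Ifitm1, S100a6, Hes6, Aoc1, Lgals3bp, Lgals3, Cldn4 and H2-Q7. The rule asked for the same sign in both mutant libraries, of which 1 is the GFP-negative fraction. Genes named by it, higher or lower, therefore need not follow the loss of Cdh1. Cldn4, which encodes a tight junction claudin, had log2 ratios of 4.43 (3.95 to 4.94) in mutant 1 and 2.21 (1.52 to 2.89) in mutant 2. S100a6, a calcium-binding protein gene, had 3.002 (2.92 to 3.09) and 2.11 (2.004 to 2.21), and Hes6, a gene of the Hes transcription factor family, had 2.08 (1.81 to 2.35) and 1.96 (1.65 to 2.26). The interferon-induced gene Ifitm1 had 2.59 (2.28 to 2.91) and 2.47 (2.12 to 2.81). AU040972, which is in the ciliated marker set, had 2.50 and 2.52. Xist, the RNA of X inactivation (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), had 10 UMIs in control, 193 in mutant 1 and 160 in mutant 2. Genes lower in both were Gsta2, a glutathione transferase, with 156 UMIs in control, 4 in mutant 1 and 0 in mutant 2, the secretoglobin Scgb1c1, with log2 ratios of -2.63 and -2.43, Igfbp6, with -2.01 and -2.05, and the aldehyde oxidase Aox3, with -1.50 and -2.13. The Gsta2 ratio in mutant 2 is a bound of at most -3.15 on the log2 scale. The other 8 genes the rule placed lowest, Scgb1a1 among them, lead the cluster itself and are not counted as results.

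Among the lists, the 5 measured keratin and squamous genes were all higher in both mutant libraries, with a median log2 ratio of 1.46 in mutant 1 (percentile 99.9) and 1.04 in mutant 2 (93.9). Measured interferon response genes, such as Bst2 and Usp18, were all higher too, with medians of 1.22 (99.98) and 1.35 (99.7), and so were those of MHC class I, with 1.14 (99.8) and 1.27 (98.6). MHC class II genes stood apart in mutant 2, with a median of 1.55 (99.8) and all 5 measured members higher, Cd74 at 1434 CPM against 557 CPM in control, and not in mutant 1, with 0.06 (5.13), a median that turned negative under each of the 3 other scalings. The free RNA median of this list was 0.94 in mutant 2, and Cd74 is among the genes that lead an AT2-like cluster. Actin and actomyosin genes had medians of 0.62 (99.0) and 0.77 (96.2), with 22 members higher in each mutant library. Tight junction genes had 0.67 (98.1) in mutant 1 and 0.49 (43.5) in mutant 2, or 0.71 and 0.58 without the 1 member that leads the cluster. Extracellular matrix and integrin genes had 0.71 (96.6) and 0.38 (22.6). Xenobiotic metabolism genes were lower, 17 of 22 in mutant 1 and 16 of 22 in mutant 2, with medians of -0.81 (0) and -1.19 (0). Without the 4 members that lead the cluster, Cyp2f2, Gsta3, Gstm2 and Fmo2, the medians of the other 18 were -0.69 and -0.96. The list still holds the club markers Cbr2 and Aldh1a1. As club markers lay less far above free RNA in both mutant libraries, these medians cannot be told apart from the make-up of the class. Secretory product genes had a median of 0.42 (58.1) in mutant 1 and -0.57 (0) in mutant 2, the latter turning to 0.52 with the shared-neighbour graph, with 31 barcodes in mutant 2, and to 1.84 without the highest doublet scores, with 20. The median gene of the class lay at 0.39 in mutant 1 and 0.51 in mutant 2, and leaving the 20 most abundant genes out of the totals moved every ratio by -0.42 and -0.44, so list medians near these values show no shift of their own.

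In club-like barcodes of each mutant library against control, the remaining lists had percentiles in the central 95% of random lists wherever they were measured. In mutant 1, cadherins and catenins had a median of 0.46 (percentile 64.1), desmosome genes 0.58 (82.5), YAP targets 0.58 (91.1), p53 targets 0.45 (63.6), chemokine and inflammation genes 0.58 (91.2), dissociation stress genes 0.37 (38.4), unfolded protein response genes 0.45 (69.0), Notch genes 0.30 (29.2) and cell death genes 0.62 (86.8). In mutant 2 the same lists had 0.60 (57.6), 0.37 (19.5), 0.50 (36.3), 0.34 (31.6), 0.64 (66.3), 0.65 (77.7), 0.60 (59.0), 0.30 (10.7) and 0.54 (50.2). The 3 measured Wnt targets had medians of 0.40 (56.6) and -0.13 (7.73), and the 3 measured proliferation genes 0.22 (18.5) and 0.09 (5.58). Genes of mesenchymal transition, with 3 measured in mutant 1 alone, had 0.84 (94.7), with Fn1 (fibronectin) at 16 UMIs in control and 99 in mutant 1, and cell extrusion and sphingosine genes 0.23 (46.1). With the totals scaled by the median gene, the medians of proliferation, dissociation stress, Notch and cell extrusion genes turned negative in mutant 1, and those of tight junction, matrix, desmosome, YAP, p53, Notch and proliferation genes in mutant 2.

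Within this class the libraries did not hold the same cells. Club markers lay above free RNA by a median log2 of 1.12 in control, with 13 of 13 markers higher, but by -0.05 in mutant 1, with 4 of 13 higher, and by 0.48 in mutant 2, with 7 of 12 higher. In mutant 1 the AT2 markers of the same barcodes lay 1.55 above free RNA, and in mutant 2 the ciliated markers lay 2.74 above it. Scgb1a1 itself stood at 267407 CPM in control, 76007 CPM in mutant 1, near the 70673 CPM of its free RNA, and 4622 CPM in mutant 2. All 24 named genes of mutant 1 and 20 of 24 of mutant 2 had the same direction in free RNA as in the class. Free RNA medians in mutant 1 and mutant 2 were 1.65 and -0.26 for keratins, 1.20 and -0.07 for interferon response, 0.64 and 0.96 for MHC class I, and 0.07 and -1.80 for xenobiotic genes. For MHC class II genes they were -2.92 and 0.94. Mutant 2 held 31 club-like barcodes with the shared-neighbour graph, 3 at a mitochondrial limit of 10% and 1 at a minimum of 1000 genes, and with each library clustered apart only control held any.

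**Figure D2:**
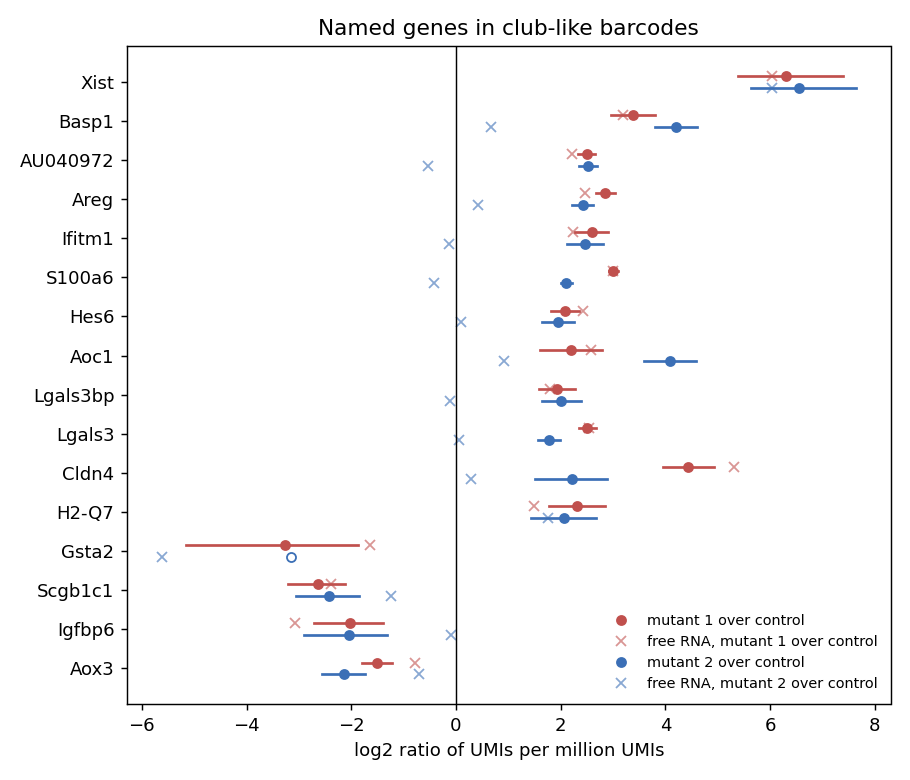
Log2 ratio of CPM in club-like barcodes for the named genes that do not lead the cluster, mutant 1 and mutant 2 over control, with lines for 95% counting intervals, open points for bounds set by a count of 0, and crosses for the same ratio in free RNA. Cldn4 lies at 4.43 in mutant 1 and 2.21 in mutant 2, and Scgb1c1 at -2.63 and -2.43.

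**Figure D3:**
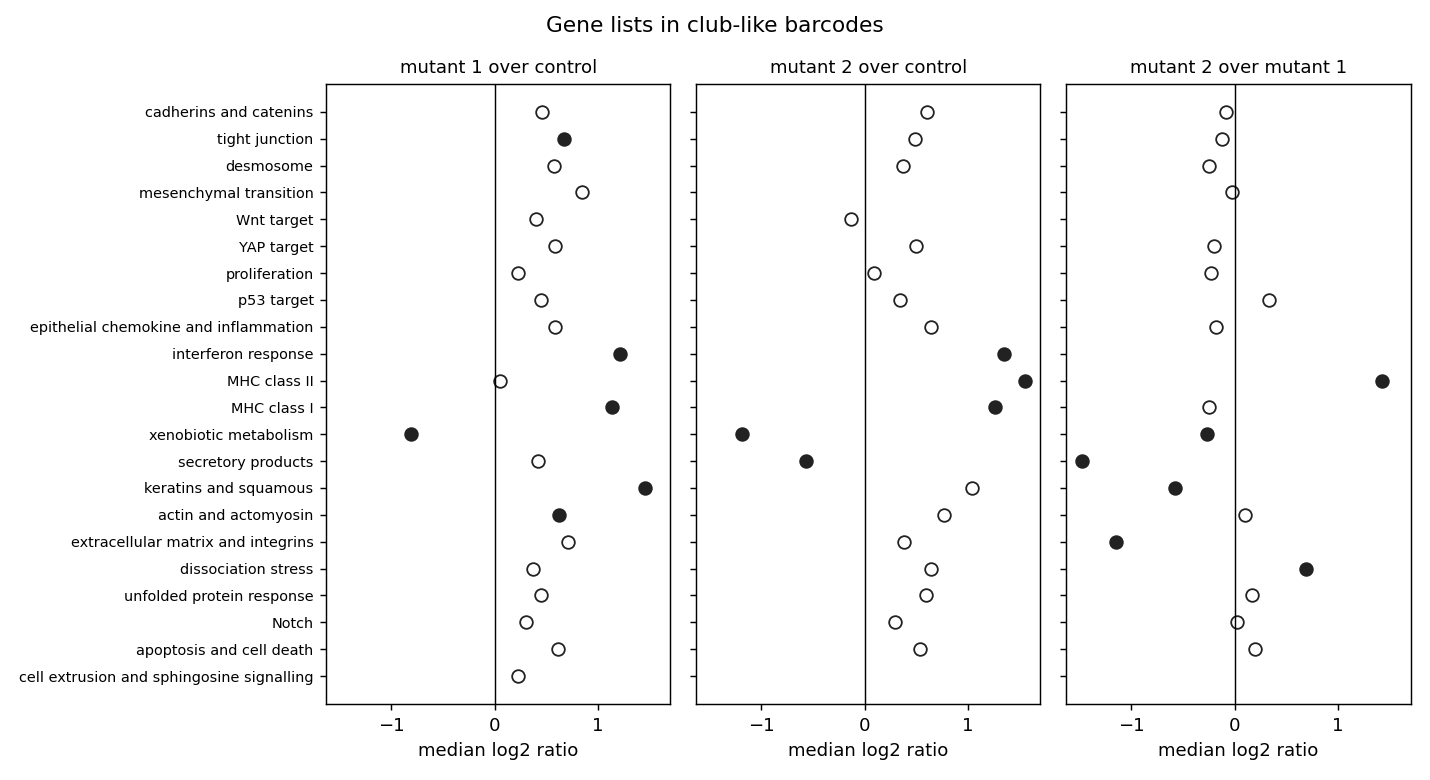
Median log2 ratio of each fixed gene list in club-like barcodes for mutant 1 over control, mutant 2 over control and mutant 2 over mutant 1, filled where the median lies outside the central 95% of 10000 matched random lists. Xenobiotic metabolism lies at -0.81 and -1.19 against control, and keratins at 1.46 and 1.04.

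Between the mutant libraries, club-like barcodes of mutant 2 held less RNA of the secretory product list and more of the MHC class II list than those of mutant 1. Scgb3a2 and Scgb3a1, secretoglobins of airway cells, had log2 ratios of -3.36 (-3.46 to -3.26) and -3.61 (-3.72 to -3.49), Muc5b, an airway mucin, -3.36 (-3.97 to -2.81), and Retnla, which encodes a resistin-like protein, -3.80 (-3.96 to -3.65). Clu (clusterin), Krtap17-1 and Rbp4 were also lower in mutant 2, at -3.74, -5.36 and -3.68. The surfactant gene Sftpc stood at 89780 CPM in mutant 2, under the 163346 CPM of its free RNA, and at 31092 CPM in mutant 1, over the 6540 CPM of its free RNA. Relative to free RNA, the AT2 markers lay the other way, at a median log2 of -0.86 in mutant 2 (0 of 14 higher) and 1.55 in mutant 1 (14 of 14). Even in AT2-like barcodes of mutant 2 these markers lay only 0.14 above free RNA, so that estimate may itself hold AT2 cells. The lysozyme gene Lyz1 had a log2 ratio of 2.32 (2.08 to 2.58). Sncg, Aebp1, Ccnd2, Acoxl and Aoc1 were higher by 2.62, 2.66, 2.37, 2.14 and 1.88, and Iglc2, an immunoglobulin light chain gene, had 238 UMIs in mutant 2 and 0 in mutant 1, a log2 ratio of at least 6.83. Cdh1 was higher in mutant 2, with a log2 ratio of 1.23 (0.92 to 1.56). Secretory product genes had a median of -1.48 (percentile 0) and MHC class II genes 1.43 (100), with Cd74 at 1.22. Keratins had -0.57 (1.57), extracellular matrix and integrin genes -1.15 (0.075), xenobiotic genes -0.27 (0.28), or 0.00 over the 14 measured members that do not lead the cluster, and dissociation stress genes 0.69 (100), Fos at 1.10 and Fosb at 1.23. Scgb3a1, Scgb3a2 and Muc5b turned positive without the highest doublet scores, where mutant 2 held 20 club-like barcodes, and so did the keratin, secretory and xenobiotic medians. The xenobiotic median also turned, to 0.05, at resolution 0.5, and the matrix median, to 0.52, with the shared-neighbour graph. Of the 16 genes, 13 had the same direction in free RNA, where the secretory median was -3.42 and that of MHC class II 3.83.

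In ciliated-like barcodes, interferon and secretory genes were higher in mutant 1 than in control, and MHC class II genes were lower there and higher in mutant 2. Of 19 measured interferon response genes, 18 were higher in mutant 1, with a median log2 ratio of 1.42 (percentile 100), and Ifi27l2a, an interferon-induced gene, had 3.26 (2.50 to 4.14) in mutant 1 and 3.98 (2.98 to 5.05) in mutant 2. MHC class I genes had medians of 0.70 (100) and 0.91 (99.9). MHC class II genes had -1.22 (0), with 6 of 6 lower, in mutant 1 and 1.74 (99.99), with 4 of 4 higher, in mutant 2. Secretory product genes had 1.48 (100) in mutant 1 and -0.87 (0) in mutant 2, and dissociation stress genes -0.82 (0) in mutant 1 and 0.01 (28.2) in mutant 2. Xist, Orm1 (orosomucoid) and Speer4c were higher in both mutant libraries, Orm1 by 2.47 (2.01 to 2.98) and 2.62 (1.85 to 3.37). Ces1d, a carboxylesterase, was lower by log2 ratios of -1.67 (-1.74 to -1.61) and -1.44 (-1.70 to -1.19), and Scgb1c1 by -1.79 and -2.89, while the predicted gene Gm281 had -1.18 and -2.48. Fsd2 had -1.24 in mutant 1 and -3.44 in mutant 2, the latter from 1 UMI (-8.75 to -0.93). Basp1 and Cdkn1c, which the rule also named, lead clusters of this class and are not counted as results. Most ciliated-like barcodes of control (995) and mutant 2 (262) lay in a cluster led by the early response genes Id1, Id3, Klf2 and Egr3, and most of mutant 1 (6461) in another, led by AU040972 and Basp1; ciliated markers lay above free RNA by a median log2 of 1.91, 3.50 and 0.46 in control, mutant 2 and mutant 1. Free RNA moved the same way for 8 of 10 named genes in mutant 1 and 10 of 10 in mutant 2, with an MHC class II median of -2.75 in mutant 1 and 0.93 in mutant 2. In mutant 1 its medians were 1.98 for interferon response and 0.95 for secretory genes, and the free RNA share of the class, estimated from Sftpc, was 0.792 against 0.221 in control.

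In AT2-like barcodes, mutant 2 held less RNA of Scgb1a1 and of the xenobiotic metabolism list than control, and more of the immunoglobulin genes Igkc, Jchain and Igha. Scgb1a1 stood at 1677 CPM in mutant 2 and 55783 CPM in control, a log2 ratio of -5.06 (-5.08 to -5.04), and Cyp2f2, Scgb3a2, Cldn10 and Lypd2 were lower by -3.12, -3.04, -4.74 and -2.52. The immunoglobulin genes Igkc and Jchain had 3352 and 382 UMIs in mutant 2 and 0 in control, log2 ratios of at least 9.54 and 6.41, and Igha had 547 UMIs and 1 UMI, a log2 ratio of 8.51 (6.03 to 13.82) that was 3.28 at a minimum of 1000 genes. Xist had a log2 ratio of 6.19 (5.56 to 6.91), and the haemoglobin gene Hbb-bs 2.38 (1.89 to 2.91). All 13 measured interferon response genes were higher, with a median of 0.46 (percentile 100), as were all 10 of MHC class I, with 0.54 (100), and 6 of 7 of MHC class II, with 0.33 (99.9). Without the 2 MHC class II members that lead the class's clusters, 4 of 5 were higher, with a median of 0.33. Xenobiotic genes had -0.81 (0), with 20 of 22 lower. Free RNA had the same direction for 9 of 10 named genes, with Scgb1a1 at -5.04 and Igkc at 12.05, and its medians were 0.68 for interferon response, 0.91 for MHC class I, 0.94 for MHC class II and -1.80 for xenobiotic genes, and AT2 markers of mutant 2 lay 0.14 above its free RNA, against 0.84 in control.

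In mesenchymal-like barcodes, Ppp1r14a, Lgals1 and Efemp1 were lower in both mutant libraries than in control, and the calcium-binding gene S100g, a marker of AT2 cells here, was higher. Ppp1r14a, a regulator of myosin phosphatase, had log2 ratios of -2.38 (-3.18 to -1.63) in mutant 1 and -1.59 (-2.12 to -1.06) in mutant 2, and Lgals1, which encodes galectin-1, -2.84 (-3.40 to -2.31) and -1.28 (-1.59 to -0.96). Efemp1, which encodes fibulin-3, had -1.52 and -1.40, and the monooxygenase gene Fmo2 -1.14 and -1.10. S100g had 1.45 (1.10 to 1.81) and 1.63 (1.31 to 1.98), Ramp1, a receptor activity-modifying protein gene, 1.57 and 1.49, and Bex3 1.42 and 1.27. Tspan8 had 1 UMI in control, with log2 ratios of 5.03 (2.50 to 10.35) and 4.40 (1.88 to 9.72), and Xist had 0 UMIs in control, with ratios of at least 3.79 and 4.26. Keratins had a median of 1.97 (percentile 99.97) in mutant 1 and -0.35 (15.4) in mutant 2, and mesenchymal transition genes -1.38 (0.565) and -0.17 (28.1). Dcn, which the rule also named, leads the cluster. The class held 148, 299 and 665 barcodes in control, mutant 1 and mutant 2, with marker levels above free RNA by a median log2 of 5.13, 5.06 and 3.50. Free RNA had the same direction for 7 of 10 named genes in mutant 1 and 6 of 10 in mutant 2, with keratin medians of 1.65 and -0.56, and its share of the class, estimated from Sftpc, was 0.721, 0.750 and 0.942.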

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

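Of the tests in this part, those asking whether Xist came from free RNA of another library were chosen after the result was seen.

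Xist RNA stood out in barcodes under the gene minimum, which lie outside the named classes and were used only as the free RNA estimate, at 184 CPM in mutant 1 and 184 CPM in mutant 2 against 2.82 CPM in control. In the kept barcodes it stood at 193 CPM in mutant 1, 197 CPM in mutant 2 and 2.42 CPM in control. Clusters left without a name, which take no part in the named classes, held 74.0% of mutant 1 barcodes against 10.9% in control. Clu, Krtap17-1, Cldn4, Retnla, Scgb3a1 and Pglyrp1 are among the genes that lead the largest of them.

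A full difference in sex, male control against female mutant animals, would make Xist and the Y-linked genes part ways. Ddx3y, Eif2s3y, Kdm5d and Uty together stood at 97.7 CPM in control, 74.8 CPM in mutant 1 and 74.5 CPM in mutant 2, with a lower ratio of 1.31 where at least 10 was asked. This speaks against a full difference only, since a male control against mutant libraries of both sexes is the pool weighed below. Free RNA from another library's cells would leave Xist higher under the gene minimum by a fold of 1.93 in mutant 2, at the free RNA share estimated over its kept UMIs. Kept barcodes were higher there, by a fold of 1.07. That prediction takes barcodes under the minimum as free RNA alone. In mutant 2 they hold cells as well, so the value does not decide. In mutant 1 the fold was 1.05 and free RNA would give 1.05, so the test cannot tell. A pool of male and female cells in the mutant libraries is a candidate explanation and cannot be told apart, as an Xist UMI and a Y-linked UMI met in 1 barcode with an odds ratio of 0.976 in mutant 1 (interval 0.867 to 1.10) and 0.909 in mutant 2 (0.589 to 1.37). The bound set in advance against a pool, a ratio above 0.9 with its interval above 0.7, was met in mutant 1, but it was judged wrong after the result was seen, because a pool at the free RNA share of 0.792 in ciliated-like barcodes would itself give 0.948 there, and in mutant 2 a pool would give 0.709 at the AT2-like share of 0.478, inside the interval, and 0.509 at the ciliated-like share of 0.306, below it. The labels give no sex, so a pool, or a difference in Xist itself, stays open, and so does free RNA from another library's cells.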

How the results depend on the processing

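The tests with the shared-neighbour graph and without the highest doublet scores were chosen after seeing the data, and so was the comparison of AT2-like barcodes. A share counts as moved when it leaves its 95% interval, and a ratio when it leaves its counting interval. With no replicates, a turn of sign is counted where the interval of a gene excluded 0 or the percentile of a list lay in the outer 5%.

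Cdh1 kept its direction in ciliated-like barcodes of mutant 1, from -1.23 to -0.22 on the log2 scale over 11 alternatives, and in club-like barcodes of mutant 2, from 0.47 to 1.80 over 7. In the main setting, ciliated markers lay above free RNA by median in these mutant 2 barcodes and below it in those of control. The latter ratio therefore compares unlike barcodes. The ciliated-like ratio does so too, as ciliated markers lay 0.46 above free RNA in mutant 1 and 1.91 in control. That class held 6821 mutant 1 barcodes in the main setting, 7029 at resolution 0.5 and 6267 with a mitochondrial limit of 10%. It held 3889 at a minimum of 1000 genes, 577 without the highest doublet scores, 362 with the shared-neighbour graph and 52 at a minimum of 250 genes. In mesenchymal-like barcodes of mutant 1 the Cdh1 ratio ranged from -2.94 to -0.74, and in AT2-like barcodes of mutant 2 from -0.41 to -0.06. In club-like barcodes of mutant 1 it lay between -0.67 and 0.40, positive under 3 of 9 alternatives. The keratin median of club-like barcodes ranged from 1.04 to 1.90 in mutant 1 and from 0.52 to 2.002 in mutant 2, the interferon median from 0.80 to 2.28 and from 0.84 to 2.07, and the xenobiotic median from -1.34 to -0.43 and from -1.70 to -0.85. The MHC class II median of mutant 2 ranged from 0.97 to 2.15, and that of mutant 1 from -0.53 to 0.61. Of 586 values of named genes under the alternatives, 315 stayed in their interval, 268 moved with their direction kept and 3 turned. Of 444 list medians, all of club-like barcodes as the only class whose lists were run under the alternatives, 272 stayed, 165 moved and 7 turned, and 58 had the other sign, all but those 7 from lists with a percentile in the central 95%. Of 73 Cdh1 ratios, 46 stayed in their interval, and of 156 shares, 45 did.

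Shares, in the order control, mutant 1 and mutant 2, depended on the clustering, and the cause was not tested. At a minimum of 1000 genes they were 31.2%, 0.0904% and 61.5% for AT2-like, 34.5%, 35.2% and 7.82% for ciliated-like, 9.67%, 0.271% and 0.20% for club-like, 0.759%, 0.362% and 9.82% for mesenchymal-like and 21.5%, 59.99% and 20.04% for unnamed barcodes. At a minimum of 250 genes they were 10.1%, 0.0627% and 12.4% for AT2-like, 3.38%, 0.142% and 0.0858% for ciliated-like, 2.42%, 0.799% and 7.41% for mesenchymal-like and 82.9%, 96.1% and 76.9% for unnamed ones, and no club-like cluster formed. With a mitochondrial limit of 10% they were 16.3%, 0.0465% and 60.2% for AT2-like, 23.2%, 20.8% and 3.06% for ciliated-like, 8.00%, 0.531% and 0.0402% for club-like, 1.82%, 0.986% and 7.66% for mesenchymal-like and 48.5%, 64.1% and 27.5% for unnamed ones. At resolution 0.5 they were 41.1%, 0.214% and 82.7%, 22.6%, 20.4% and 3.77%, 20.2%, 1.27% and 4.02%, 1.76%, 0.744% and 6.83%, and 12.2%, 75.9% and 1.46% for the same classes in the same order. With the libraries clustered apart they were 31.4%, 0% and 0%, 52.6%, 0% and 0%, 8.74%, 0% and 0%, 1.83%, 1.30% and 7.82%, and 1.93%, 97.7% and 69.1%. With the shared-neighbour graph they were 37.8%, 0.139% and 77.9%, 15.2%, 1.05% and 2.24%, 9.43%, 7.71% and 0.332%, 1.87%, 1.06% and 7.35%, and 32.9%, 81.6% and 10.5%. Without the highest doublet scores ciliated-like shares were 30.7%, 1.76% and 10.3%, club-like ones 8.17%, 0.796% and 0.226% and unnamed ones 17.7%, 93.8% and 1.67%. Goblet-like and tuft-like clusters, absent from the main setting, formed under some alternatives. Mutant 1 held 1908 goblet-like and 1437 tuft-like barcodes with a mitochondrial limit of 10% (control 17 and 22), 1308 and 469 with the shared-neighbour graph (39 and 9), and 147 and 127 at a minimum of 1000 genes (10 and 1). With the libraries clustered apart, control held 178 goblet-like, mutant 2 held 39, and mutant 1 held 272 tuft-like barcodes. Mutant 2 also formed an erythroid-like cluster of 1369 barcodes with the libraries clustered apart, led by Hbb-bs, and a B-like cluster of 328 at a minimum of 250 genes, led by Igkc, Igha and Jchain, genes that were higher in AT2-like barcodes of mutant 2 in the main setting.

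The Cdh1 log2 ratio to control left its interval under these alternatives, and the cause was not tested. At a minimum of 1000 genes it was -1.13 in ciliated-like barcodes of mutant 1 and -0.29 in AT2-like barcodes of mutant 2. At a minimum of 250 genes it was -0.22 and 0.36 in ciliated-like barcodes of mutant 1 and mutant 2, and -0.24 in AT2-like barcodes of mutant 2. With a mitochondrial limit of 10% it was 0.38 in club-like barcodes of mutant 1. With the shared-neighbour graph it was 1.53 in club-like barcodes of mutant 2, -0.87 in ciliated-like barcodes of mutant 1 and -0.21 in those of mutant 2, and club-like barcodes of mutant 2 over mutant 1 were at 1.65. Without the highest doublet scores it was 0.33 and 1.71 in club-like barcodes of mutant 1 and mutant 2. Without the 20 most abundant genes in the totals it was -0.67 and 0.55 there, with median-of-ratios scaling -0.64 and 0.47, and with the mean over barcodes -0.57 and 0.59. In ciliated-like barcodes of mutant 1 the last 2 gave -0.90 and -0.87. After thinning to 3000 UMIs it was 0.40 and -1.23 in club-like and ciliated-like barcodes of mutant 1 and -0.41 in AT2-like barcodes of mutant 2. With free RNA subtracted it was -0.78 and -2.94 in ciliated-like and mesenchymal-like barcodes of mutant 1, and 1.80 and -0.30 in club-like and AT2-like barcodes of mutant 2.

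These values turned sign in club-like barcodes, and the cause was not tested. Without the highest doublet scores, where mutant 2 held 20 such barcodes, the secretory median of mutant 2 over control was 1.84. Against mutant 1 it was 1.08, with the keratin median at 0.45, the xenobiotic median at 0.35, Scgb3a1 at 1.05, Scgb3a2 at 0.75 and Muc5b at 1.29. With the shared-neighbour graph, with 31 barcodes, the secretory median over control was 0.52 and the matrix median over mutant 1 was 0.52. At resolution 0.5 the xenobiotic median over mutant 1 was 0.054.

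In these small classes a gene with 0 UMIs in 1 library gives only a bound, and a bound that leaves the direction open was given no value, a rule set after such bounds were seen with the other sign. Among others, this held for Gsta2 and Esr1 in club-like barcodes of mutant 2 over control with the shared-neighbour graph and without the highest doublet scores, for Fsd2 in ciliated-like barcodes of mutant 2 at a minimum of 1000 genes, and for the secretory and xenobiotic medians of mutant 2 over mutant 1 with the shared-neighbour graph. Mutant 2 gave no club-like comparison at minimums of 1000 and 250 genes, with a mitochondrial limit of 10%, with the libraries clustered apart or after thinning, and mutant 1 gave none at 250 genes and with the libraries clustered apart. Free RNA could not be subtracted in club-like barcodes of mutant 1. Depth limits all of this, since thinning to 3000 UMIs kept 56 of 506 club-like barcodes in mutant 1, 252 of 1876 in control and 2 of 636 in mutant 2. No paired analysis was possible because the replicate numbers of the mutant libraries only follow the order of the sample records and control has 1 library, and this rests on the design and not on a test.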

Other observations

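Of the tests in this part, those on club markers over free RNA and on Scgb1a1 in mutant 2 were chosen after the result was seen, and so were the comparisons within clusters.

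Most mutant 1 barcodes lay in 3 clusters without a name that hold airway secretory RNA. Cluster 0 (211 barcodes in control, 10407 in mutant 1 and 12 in mutant 2) is led by Clu, Krtap17-1, Cldn4 and Tnip3, cluster 2 (470, 8531 and 27) by Retnla, Clu, Krtap17-1 and Scgb3a1, and cluster 4 (152, 6601 and 67) by Pglyrp1, Clca1, Scgb3a1 and Reg3g. The nearest marker set was transitional for cluster 0 and goblet for clusters 2 and 4, at a mean log2 of 0.151, -0.020 and 0.198 over free RNA, so cluster 4 missed the goblet name by little, under a limit of 0.2 set after the naming was seen. Within clusters 0, 2 and 4, mutant 1 over control gave xenobiotic medians of -0.60, -0.80 and -1.40 on the log2 scale (percentile 0 in each) and keratin medians of 0.90, 1.20 and 0.90 (percentile 99.78 or more). Interferon response genes had 0.78, 2.02 and -0.02, MHC class I genes 0.56, 1.33 and -0.60, MHC class II genes -1.24, -0.33 and -2.42, and secretory product genes 0.50, 0.70 and -0.92. In free RNA, keratins had 1.70, above each of the 3 clusters, interferon response genes 1.98 over the members measured in clusters 0 and 4 and 1.93 over those in cluster 2, MHC class I genes 0.64, secretory product genes 0.95, and MHC class II genes -2.92 in clusters 0 and 2 and -2.75 in cluster 4, while xenobiotic genes had 0.07. Cdh1 was lower in mutant 1 in each, with log2 ratios of -1.15 (-1.49 to -0.80), -0.38 (-0.66 to -0.08) and -0.79 (-1.15 to -0.40), where the median gene lay at 0.03, 0.45 and 0.06. Scgb3a1 was higher in mutant 1 in clusters 0 and 2, at 2.28 and 1.17, and lower in cluster 4, at -1.21. In cluster 4 at least, these ratios compare unlike barcodes, as Muc5b stood there at 1285 CPM in control and at 367 CPM in mutant 1, near the 395 CPM of its free RNA. Cluster 12 (48 barcodes in control, 0 in mutant 1 and 25 in mutant 2) is led by Igkc, Jchain, Igha and Mki67.

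For the genes that differ between club-like barcodes of mutant 1 and control, a difference in depth stays open, although after thinning to 3000 UMIs the median absolute log2 ratio of the 24 named genes did not fall (a fall of -31.2%, that is, a larger median). This met the bound set in advance, which was judged wrong after the result was seen, since thinning does not change the expected ratio of summed UMIs, whatever the cause (the median moved by 8.13% in the same 56 and 252 barcodes), so the value rests on which barcodes are left and decides nothing. Free RNA as most of the RNA of these barcodes stays open and may explain the differences, since club markers lay at a median log2 of -0.046 over free RNA in mutant 1 and 1.12 in control, and all 24 genes had the same direction in free RNA. It is not the whole of that RNA, because the AT2 markers of the class lay 1.55 above free RNA and Sftpc stood at 31092 CPM against 6540 CPM. The loss of Cdh1, the biological explanation that the design gives, was not tested, with 1 control library and fractions that the labels do not tell apart.

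For the genes that differ between club-like barcodes of mutant 2 and control, barcodes of another type, or free RNA, in place of club cells may be the source. Scgb1a1 stood at 0.0173 times its control level there, but it is itself among the genes to be explained. It was also low in free RNA, at 3507 CPM in mutant 2 against 115507 CPM in control, so it says little about this class. Club markers lay 0.48 above free RNA in mutant 2 and 1.12 in control. Ciliated markers lay 2.74 above it in mutant 2, with 15 of 15 higher, and at -0.32 in control, with 1 of 15 higher. The class in mutant 2 thus held ciliated RNA beyond free RNA, and that in control largely did not. The loss of Cdh1 stays open here too, as it was not tested and the labels do not say whether mutant 2 is the GFP-positive fraction.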
